A study of Mus musculus with 4 samples.

How the data were processed

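The series holds single-cell RNA libraries of mouse medial habenula tissue, dissociated with papain and loaded on the 10x Chromium platform. It has 4 libraries in 4 groups: wild type or Hhip mutant, each after saline or nicotine, with 1 library per group. Per the labels, nicotine was given at 1.0 mg per kg under the skin on 3 consecutive days, and tissue was taken 24 hours after the last injection. Neither the number of animals behind a library nor the zygosity of the mutants is given. The deposited matrices hold raw UMI counts of 32285 genes per barcode, with no normalization, and the same gene order in every library. Per the submitters' processing notes, Cell Ranger, Seurat, Scanpy 1.5.1 and the mouse build mm10 were used, with no role or order stated. Of the gene identifiers, 32158 (99.6%) were found in the GENCODE annotation M21, which was used to place Hhip on the genome. The series also holds 4 lists of cell barcodes without values, which join the barcodes of library pairs and were not used.

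The libraries hold 37541 barcodes and 44956591 UMIs in total. Barcodes were kept with at least 200 detected genes and at most 20% mitochondrial UMIs, which left 30068. Scrublet was run within each library through Scanpy 1.11.5 with its default expected rate. It called 10 doublets in WT_Saline (0.123%), 1 in Mutant_Saline (0.00529%), 13 in WT_Nicotine (0.463%) and 13 in Mutant_Nicotine (6.02%). The doublet caller has not worked on the large libraries, so that doublets remain among the 30031 cells analysed. An alternative removes the highest-scoring cells of each library at the expected rate. Cells of all libraries were clustered together on 2000 variable genes, 30 principal components, 20 neighbours and the Leiden algorithm at resolution 1 (4 iterations, seed 1), with no correction between libraries. Hhip and the lists of Hedgehog, nicotinic receptor, immediate early, stress, mitochondrial, ribosomal and sex-linked genes were kept out of the clustering.

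Each of the 29 clusters was named from 23 lists of cell type markers. A name needed a mean log2 fold of at least 1 over the other clusters, at least 3 markers at 2-fold, and a margin of 0.5 over the next list, with a pseudocount of 10 CPM. No name was given where a list of another lineage also reached a mean log2 fold of 1 with at least 2 markers. Lists of neurons, of the oligodendrocyte lineage, of immune cells and of vascular cells with fibroblasts each counted as 1 lineage. Cluster 15 is thus named pericyte or smooth muscle, although the endothelial list reaches 2.03 there. The 10 leading genes of each cluster were read beside the name. Classes carry the ending "-like" since the names rest on these markers alone. Medial habenula neuron-like cells are clusters 0 and 11, ependymal-like cells clusters 3 and 8, choroid plexus-like cells cluster 5, astrocyte-like cells clusters 1, 10 and 19, oligodendrocyte-like cells clusters 4 and 6, endothelial-like cells cluster 2 and microglia-like cells cluster 9. Lateral habenula neuron-like cells are cluster 12, cortical or hippocampal neuron-like cells clusters 7 and 17, and oligodendrocyte precursor-like cells cluster 14. Cluster 16, where no list stands out, and clusters 13, 25, 26, 27 and 28, with markers of more than 1 lineage, are unnamed.

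Counts were summed over the cells of a class in each library and scaled to the class total as CPM. The 4 comparisons were mutant over wild type under saline and under nicotine, and nicotine over saline in wild type and in mutant, in each class with at least 50 cells in both libraries. The difference of the nicotine ratios between genotypes was taken where all 4 libraries had that many. With 1 library per group there is no test of a pair of libraries, and no gene was called. A test of genotype or nicotine over both pairs, which would leave 1 degree of freedom and assume that both act alone, was not made. Each pair of values stands with a log2 ratio and its exact conditional binomial interval at 95% confidence. Levels have Poisson intervals, shares have Clopper-Pearson intervals, and a difference of ratios has an interval from its 4 Poisson counts. Hhip less the level of astrocyte-like cells, taken as a share of UMIs or as counts per cell, was added after seeing the data, with an interval from 20000 gamma draws of each count. All of these cover counting error only, not the spread between animals or preparations, so every comparison is of libraries and not of conditions. Where a group has 0 counts, a fold is taken against a floor of 3 counts per library and class, and written as "at least".

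The 26 gene lists were Hedgehog signalling, nicotinic acetylcholine receptor subunits with their assembly factors, cholinergic transmission, habenular neuropeptides and receptors, glutamate release and receptors, GABA receptors, presynaptic vesicle machinery, immediate early genes, heat shock and dissociation stress, mitochondrially encoded genes, nuclear oxidative phosphorylation, ribosomal proteins, glycolysis, the unfolded protein response, the interferon response, microglial activation, microglial homeostatic genes, myelin, cholesterol synthesis, reactive astrocyte genes, astrocyte transport, the blood-brain barrier, Wnt signalling, extracellular matrix, potassium and pacemaker channels, and sex-linked genes. A list is given as the median log2 ratio of its members with at least 20 summed counts. Beside it stands the percentile of that median among 10000 random lists of as many genes with like expression, as a description of these libraries. Where members are at 0 in 1 library the median is also given with those members at their bound, and lists in the shallow library are given as summed counts.

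The genes named are Hhip, the Hedgehog and nicotinic receptor members with at least 20 counts, the 8 highest and 8 lowest genes of the main class by the interval bound nearest 0 among genes with at least 50 counts, the 2 highest and 2 lowest of each other class, and the members of each list with the most counts. Mitochondrial, ribosomal, haemoglobin and sex-linked genes, unnamed gene models and markers of other classes were left out of the ranking. Not every gene that the rule takes is named in the text. The main class is medial habenula neuron-like, or ependymal-like where the former has under 50 cells. Single genes of other lists that the text adds were chosen after their values were seen.

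Alternatives were at least 500 genes per cell, at most 10% mitochondrial UMIs, every barcode without a filter, median-of-ratios size factors, scaling without mitochondrial and haemoglobin genes, doublets kept, resolutions 0.5 and 2, gene means centred within each library, list members with at least 5 or 100 counts, both libraries thinned to 1 total, and each cell thinned to 500 UMIs. The groups, the classes' markers, the gene lists, the rule for named genes, these comparisons and these alternatives were set before the data were examined. Added after seeing the data were removal of the highest-scoring doublets, scaling without Gm42418, cluster 11 only, cluster 3 only, centring for the comparison under saline, and list sums.

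The interval and the list percentile were tested on simulated data, by Poisson draws from the pooled profile of the main class at the UMI totals of both libraries, with 200 genes altered, 50 at each of 4 folds. For genotype under saline 95.8% of 10993 unaltered genes lay inside their interval, and the intervals held folds of 2, 4, 0.5 and 0.25 for 96.0%, 92.0%, 90.0% and 100.0% of genes, with median log2 ratios of 0.96, 1.99, -1.01 and -1.99. For genotype under nicotine 98.1% of 2705 unaltered genes lay inside, and the folds were held for 98.0%, 100.0%, 100.0% and 98.0%, with medians of 0.97, 2.01, -1.54 and -3.22. For nicotine in wild type 98.2% of 8960 lay inside, and the folds were held for 98.0%, 98.0%, 96.0% and 100.0%, with medians of 0.81, 1.89 and -1.64 and none for 0.25, where the typical gene had 0 counts. For nicotine in mutant 98.5% of 9931 lay inside, and the folds were held for 98.0%, 90.0%, 100.0% and 100.0%, with medians of 1.03 and 1.94 and none for the lower folds. Of random lists without a change, 4.5%, 2.5%, 4.0% and 2.0% lay outside the central 95 percentiles in these comparisons, and a list doubled in every member lay at percentiles 100, 99.99, 99.99 and 99.67. Folds below 1 came out larger than simulated where the smaller library is shallow.

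Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.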

Results

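The libraries differ widely in depth. The wild type saline library holds 8234 barcodes with a median of 714 UMIs, the mutant saline library 19226 with 1100.0, the library labelled wild type, nicotine 2879 with 787, and the mutant nicotine library 7202 with 60.0. No barcode of the mutant nicotine library has more than 658 UMIs, while those of the other 3 start at 500. The filter kept 98.9%, 98.3% and 97.6% of barcodes in the first 3 and 3.00% in the last, which leaves 8136, 18896, 2796 and 203 cells. Values from the mutant nicotine library therefore rest on few cells, and small differences were not detectable there at this depth.

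Hhip, which encodes a membrane protein that binds Hedgehog ligands and holds the pathway back, was lower in every other library than in wild type saline. Over every barcode it stood at 96.9 CPM (90.2 to 104; 789 counts) in wild type saline, 25.7 (24.0 to 27.5; 843 counts) in mutant saline, 10.0 (6.96 to 14.0; 34 counts) in the library labelled wild type, nicotine and 23.5 (12.9 to 39.5; 14 counts) in mutant nicotine. The lowest value is that of the library labelled wild type, nicotine, its interval overlaps that of mutant nicotine, and 2.58% of its cells are medial habenula neuron-like against 39.4% in wild type saline. Per 1000 counts of the 8 habenular markers Hhip was 78.6, 52.4, 39.3 and 29.4, and the order of the last 2 depends on the marker, with 5 of 8 giving less in mutant nicotine. In medial habenula neuron-like cells (clusters 0 and 11) Hhip was 159 CPM (146 to 174; 3206 cells) in wild type saline and 77.6 (67.2 to 89.3; 2105 cells) in mutant saline, a log2 ratio of -1.04 (-1.28 to -0.80). In cluster 11 alone it was 174 against 96.3, or -0.85 (-1.18 to -0.53). Astrocyte-like cells, read here as background, differ too, with 81.2 against 17.3 CPM. They come from different clusters, with 823, 37 and 4 cells of clusters 1, 10 and 19 in wild type saline and 2284, 1168 and 380 in mutant saline. Less the astrocyte-like level as a share of UMIs the Hhip ratio was -0.37 (-0.88 to 0.33) in the class and -0.23 (-0.78 to 0.48) in cluster 11. With that level as counts per cell it was -0.72 (-1.11 to -0.29) and -0.75 (-1.12 to -0.38). Its size, and whether it lies beyond counting error, thus depend on the background. The library labelled wild type, nicotine has 2 Hhip counts in 72 such cells (36.8 CPM, 4.45 to 133), and mutant nicotine has 0 in 29 cells, with an upper bound of 507. Hhip spans 13 exons on the minus strand of chromosome 8. Whether the counted 3' end lies inside the altered part is not given in the labels, so transcript from a mutant allele can still be counted.

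**Figure D1:**
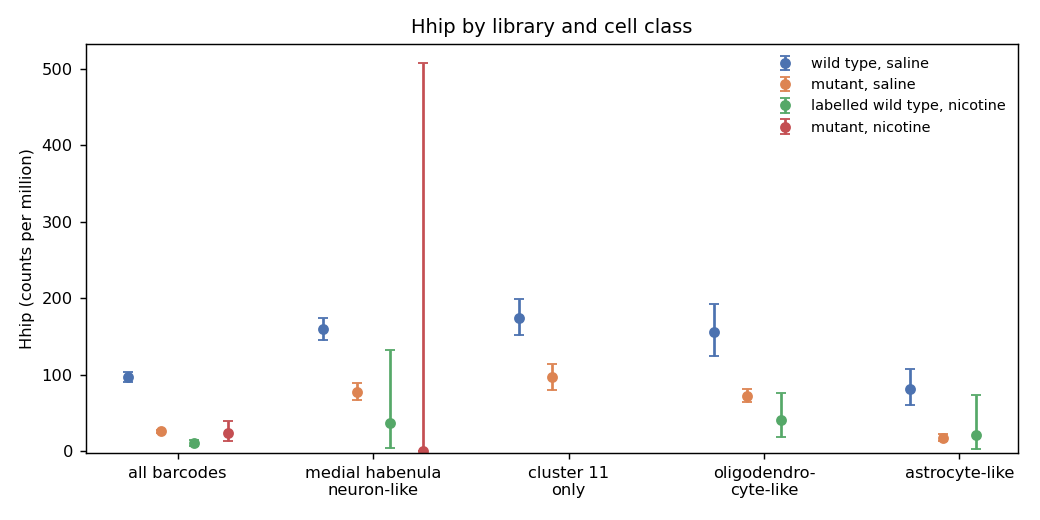
Hhip in CPM (y axis) per library (colours) over all barcodes and in 4 groups of cells (x axis), with points for the level and bars for the 95% Poisson interval, which covers counting error only. Over all barcodes the levels are 96.9, 25.7, 10.0 and 23.5, and the intervals of the last 2 overlap.

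The cells form neuronal, glial, vascular and ventricular classes in proportions that differ between the libraries. Astrocyte-like cells made up 10.6% of wild type saline, 20.3% of mutant saline and 5.01% of the library labelled wild type, nicotine, with 0 of 203 cells in mutant nicotine (upper bound 1.80%). Ependymal-like cells, which line the ventricle, were 13.6%, 8.89%, 19.8% and 36.5% (29.8 to 43.5), and choroid plexus-like cells 3.44%, 5.29%, 12.7% and 34.0% (27.5 to 41.0). Different clusters hold the ependymal-like cells: 822 of cluster 3 and 283 of cluster 8 in wild type saline, 997 and 683 in mutant saline, 185 and 370 in the library labelled wild type, nicotine, and 73 of 74 cells in cluster 3 in mutant nicotine. Oligodendrocyte-like cells were 9.16%, 13.7%, 10.4% and 0.493%, from cluster 6 in wild type saline (710 of 745 cells) and mostly cluster 4 in mutant saline (1738 cells) and the library labelled wild type, nicotine (274 cells). Cortical or hippocampal neuron-like cells, from outside the habenula, were 0.934%, 9.29%, 6.40% and 0%. Clusters 7 and 17 hold 72 and 4 of them in wild type saline, 1346 and 409 in mutant saline, and 32 and 147 in the library labelled wild type, nicotine. Lateral habenula neuron-like cells were 3.58%, 3.90%, 0.536% and 11.3%. The unnamed cluster 13 holds 600 of its 807 cells from the library labelled wild type, nicotine, so its size is not read as that of a cell type.

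Medial habenula neuron-like cells were 39.4% (38.3 to 40.5) of wild type saline, 11.1% (10.7 to 11.6) of mutant saline, 2.58% (2.02 to 3.23) of the library labelled wild type, nicotine and 14.3% (9.78 to 19.9) of mutant nicotine. These shares stand as values without an order, because cluster 0 is led by Pde6a, Sec61a1, Mc1r and Gm42418, and the first 3 were lower in mutant saline than in wild type saline in all 13 classes compared. Cluster 11, led by habenular genes such as Tac2, made up 6.93%, 3.07%, 0.322% and 0%.

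**Figure D2:**
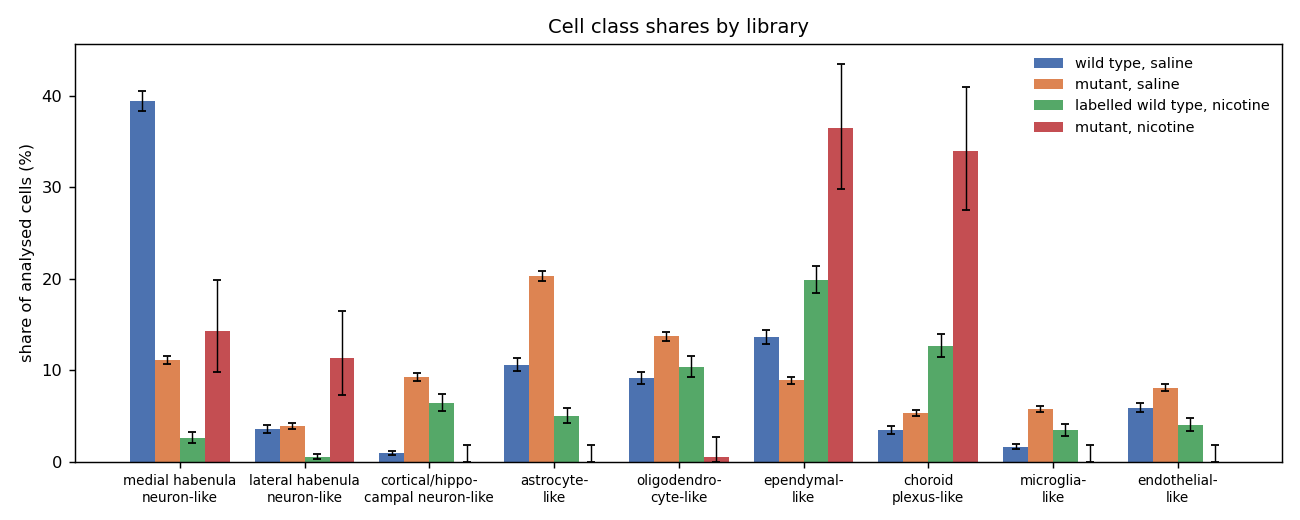
Share of analysed cells in percent (y axis) for 9 cell classes (x axis) in each library (colours), with bars from 0 and 95% Clopper-Pearson intervals that cover counting error only. Ependymal-like cells are 36.5% and choroid plexus-like cells 34.0% of the 203 mutant nicotine cells, and astrocyte-like cells are 0% of them.

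Hhip in wild type saline was not confined to habenular neurons. With each cell thinned to 500 UMIs, 7.52% of medial habenula neuron-like cells (median depth 715 UMIs) and 7.79% (5.96 to 9.95) of oligodendrocyte-like cells (669) held a Hhip UMI, against 4.05% (2.84 to 5.59) of astrocyte-like cells (639.5), read here as background, and 10.3% of cluster 11 (1599). The levels were 156 CPM in oligodendrocyte-like and 81.2 in astrocyte-like cells. In mutant saline the thinned shares were 3.61% (medial habenula, 826 UMIs), 3.90% (oligodendrocyte, 1410.0) and 0.861% (astrocyte, 942), and oligodendrocyte-like Hhip was 72.1 CPM, a log2 ratio of -1.11 (-1.46 to -0.75). Less the astrocyte-like level this was -0.44 (-1.12 to 0.67), and the cells come from different clusters, as given above, so no direction is given. Ptch1, the Hedgehog receptor, sat chiefly in astrocyte-like cells: 22.8% of them held a UMI when thinned in wild type saline and 19.3% in mutant saline, against 5.55% and 4.28% of medial habenula neuron-like cells. The astrocyte-like cells come from different clusters in these libraries, as given above, so no direction is given for Ptch1 in them. Chrna3, a subunit of habenular nicotinic receptors, was found in 6.99% of thinned medial habenula neuron-like cells and 8.87% of cluster 11 in wild type saline, above 3.94% of astrocyte-like cells, and in 6.79%, 8.28% and 2.22% in mutant saline.

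Under saline, medial habenula neuron-like cells of the mutant library held more transcript of energy metabolism and protein synthesis, more Gpr151 and Tac2, and less Kcnma1, Snap25 and Slc17a6 than those of the wild type library. Cluster 0 holds 2642 of the 3206 wild type cells and 1525 of the 2105 mutant cells of the class. All 29 nuclear oxidative phosphorylation genes were higher, with a median log2 ratio of 1.19 (percentile 100 of random lists), among them Cox8a at 804 against 290.1 CPM and Cox6c at 802 against 332. All 34 ribosomal protein genes were higher (median 1.14, percentile 100; Rps29 1826 against 891, Rpl37 1255 against 487), as were 11 of 13 mitochondrially encoded genes (0.77, percentile 99.6; mt-Co1 0.78) and 15 of 16 glycolytic genes (0.59, percentile 99.9; Gapdh 1.52, Aldoa 0.76). Ribosomal protein transcripts were 3.06% of all UMIs in wild type saline and 5.48% in mutant saline, and Gm42418 was 11.1% and 2.18%. Over all cells analysed, oxidative phosphorylation genes held 59776 of 8012833 UMIs in wild type saline and 530549 of 32342828 in mutant saline. The higher oxidative phosphorylation and ribosomal values are thus shared by the whole library and not particular to this class. Scaling without Gm42418 lowers every log2 ratio of this class by 0.16 (a shift of -0.16), so no direction is given for a list or gene within that of 0. It leaves 29, 34, 8 and 14 members of these 4 lists higher. In cluster 11 alone the medians were 0.99 for oxidative phosphorylation, 0.75 for ribosomal proteins, 0.58 for mitochondrially encoded genes and 0.53 for glycolysis.

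Habenular neuropeptide and receptor genes stood higher in most members, while the nicotinic receptor list lay near 0. Of the habenular neuropeptides and their receptors 16 of 18 were above 0, or 11 without Gm42418 (median 0.28, percentile 95; cluster 11 0.26). The median is 0.11 without Gm42418 and below 0 over every barcode, where the libraries' cell make-up differs. Gpr151, an orphan receptor of habenular neurons, was 258 against 107 CPM (1.27, 1.08 to 1.46), Tac2, which encodes neurokinin B, 467 against 256 (0.87, 0.74 to 1.00), and Gabbr1 0.28. Tac2 is also a marker behind the class name and leads cluster 11, and Gpr151 is on the lateral habenula list. For nicotinic receptor subunits and assembly factors 6 of 8 were above 0, or 4 without Gm42418, with a median of 0.16 (percentile 76.7) that drops just below 0 without Gm42418. Chrna3 was 186 against 135 CPM (0.45, 0.26 to 0.65), with 0.66 (0.39 to 0.93) in cluster 11 and 0.04 (-0.26 to 0.34) in cluster 0, and its share of thinned cells was not higher (6.79% against 6.99%). Tmem35a, an assembly factor, was 95.8 against 68.8 (0.48, 0.21 to 0.75). Chrna4 was 50.4 against 37.6 (0.42, 0.05 to 0.80), Chrnb4 89.1 against 75.9 (0.23, -0.04 to 0.50), and Chrnb3 72.1 against 85.6 (-0.25, -0.53 to 0.03). Ric3 was at -0.21, Lynx1 at 0.09 and Chrnb2 at 0.06. Over every barcode Chrna3 was at -1.22 and Chrna4 at -0.80.

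The Hedgehog list lay near 0 in these cells, with 7 of 20 members above 0, or 3 without Gm42418, a median of -0.11 (percentile 16.4) and a summed ratio of -0.12. Hhip was its member with the clearest difference in CPM. Less the astrocyte-like level as a share of UMIs, that difference is within counting error (-0.37, -0.88 to 0.33). With that level as counts per cell it is -0.72 (-1.11 to -0.29). Ptch1 was 87.1 against 94.2 CPM (-0.11, -0.37 to 0.14) and Scube1 1014 against 1224 counts (0.02). Csnk1a1 was at -0.10, Kif3a at -0.23 (-0.43 to -0.02), Spop at -0.07, Gsk3b at 0.05, Ift88 at -0.10 and Sufu at 0.08. With fewer counts, Gas1, a Hedgehog co-receptor, was at 0.97 (0.28 to 1.68), Gpr161 at -1.05 (-2.10 to -0.09), Boc at -1.29 (-2.91 to 0.10), Gli1 at 0.71 (-0.33 to 1.78) and Smo at -0.74 (-1.53 to 0.01). The potassium and pacemaker channels were lower in 12 of 17 (median -0.18, percentile 3.16), with Kcnma1, the large-conductance calcium-activated channel, at 1442 against 2085 CPM (-0.53, -0.59 to -0.47) and Kcna2 at -0.36. Kcnma1, a leading gene of cluster 0, was at -0.89 (-0.99 to -0.80) in that cluster and -0.37 (-0.44 to -0.29) in cluster 11.

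Lists of stress, immune and glial genes make up the rest of the saline comparison in this class. Immediate early genes were higher in 17 of 25 (15 without Gm42418; 0.29, percentile 97.1; Fos 91.8 against 51.8 CPM, 0.83; Jund 0.68, Nr4a2 0.53), but at 0.045 in cluster 11 alone, -0.045 with at most 10% mitochondrial UMIs and -0.15 with centring within each library, so no direction is given. Heat shock and dissociation stress genes were higher in 13 of 16 (11 without Gm42418; 0.38, percentile 97.7; Hsp90ab1 0.37, Hspa8 0.13), interferon response genes in 13 of 16 (10 without it; 0.34, percentile 96.6; B2m 0.14, Ifitm3 -0.16) and microglial activation genes in 9 of 13 (8 without it; 0.55, percentile 99.5; Apoe 0.89, Cd63 1.02). Cholesterol synthesis stood at 0.23 (percentile 91.1; Hmgcs1 -0.07), reactive astrocyte genes at 0.24 (83.1; Vim 0.11) and astrocyte transport at 0.19 (78.0; Glul 0.79, Aqp4 -0.58). Lower were extracellular matrix in 10 of 13 (-0.38, percentile 0.33; Sparc 0.50, Col4a1 -0.46), the blood-brain barrier list in 10 of 12 (-0.29, 0.5; Tfrc, the transferrin receptor, -0.35; Lef1 -0.76) and Wnt signalling in 9 of 15 (-0.27, 0.955; Apc -0.61, Tcf7l2 0.12). Presynaptic vesicle genes (0.02, percentile 37.2; Snap25 477 against 673 CPM, -0.50; Syt1 -0.01), cholinergic transmission (-0.09, 19.7; Slc5a7 -0.15, Chat -0.09) and sex-linked genes (-0.16, 13.1; Xist -0.26, Tsix -1.72) lay near 0, and presynaptic genes are below 0 without Gm42418 or with size factors. The medians and sums differ in sign for glutamate genes (-0.06 and 0.08, percentile 18.3; Slc17a6, the vesicular glutamate transporter, -0.39; Gria2 0.30; Slc17a7 0.19), GABA receptors (-0.09 and 0.10, 15.0; Gabrb1 -0.31), myelin (0.16 and -0.01, 74.4; Mbp 0.76), the unfolded protein response (0.12 and -0.02, 66.8; Hspa5 -0.20) and microglial homeostatic genes (-0.12 and 0.21, 30.9).

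Single genes with the clearest higher values in the mutant saline library include abundant housekeeping transcripts. Fth1, the ferritin heavy chain, was 3102 against 794 CPM (1.97, 1.90 to 2.03), Ubb, a ubiquitin gene, 975 against 275 (1.83, 1.71 to 1.94), Ppia, cyclophilin A, 1076 against 326 (1.73, 1.62 to 1.83) and Gstp1, a glutathione transferase, 46.1 against 5.79 (2.99, 2.27 to 3.80). The histone gene Hist1h2ap was at 4.12 (2.83 to 5.79), Slc24a5 at 2.30 (1.82 to 2.81), Dsp at 2.61 (1.66 to 3.70) and Rprm at 2.24 (1.64 to 2.88). The lowest were Sec61a1, a subunit of the protein translocon, at 219 against 2831 CPM (-3.69, -3.82 to -3.57), Pde6a, a phosphodiesterase known from photoreceptors, at -4.10 (-4.46 to -3.76), and Mc1r, a melanocortin receptor, at -4.48 (-5.21 to -3.84). Il23a was at -4.06 (-5.97 to -2.65) and Dppa2, with 3 counts in mutant saline, at -4.23 (-6.54 to -2.62). Npffr1 was at -3.50, Cd74 at -3.39 (-5.06 to -2.09) but 0.20 over every barcode, and Gnaz at -1.98 (-2.27 to -1.70). Sec61a1 and Pde6a were lower in all 13 classes compared. None of these differences has a replicate check.

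**Figure D3:**
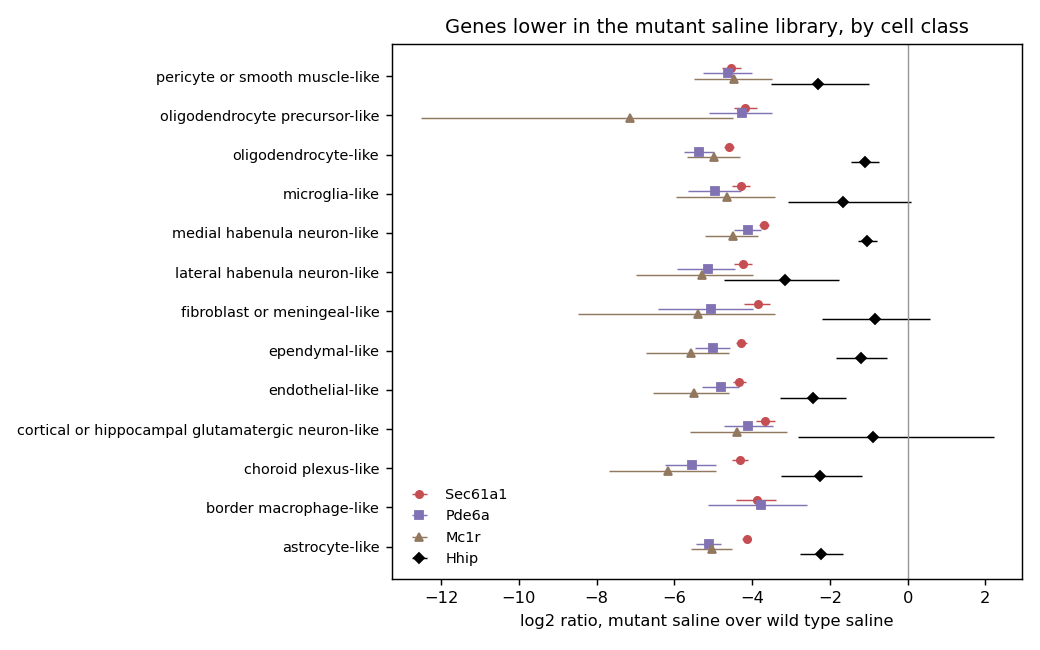
Log2 ratio of CPM in mutant saline over wild type saline (x axis) for 4 genes (colours) in the classes compared (y axis), with the ratio as points and 95% conditional binomial intervals as bars, which cover counting error only; members with under 20 counts are left out. Sec61a1 lies between -4.58 and -3.66 in all 13 classes, and Hhip between 0 and the split genes.

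Outside the neurons, ependymal-like cells differed under saline in immediate early and Hedgehog genes, and endothelial-like cells in interferon response genes. Size factors shift these classes by 0.17 and 0.11 and turn no list named here. Ependymal-like cells held more immediate early gene transcript in mutant saline, higher in 21 of 25 (median 1.06, percentile 100; summed in cluster 3 alone 0.96), with Egr1 at 165 against 32.7 CPM (2.33, 1.92 to 2.77), Fosb at 2.87 (1.92 to 4.02) and Fos at 2.07 (1.86 to 2.30), or 1.59, 1.69 and 1.45 in cluster 3 alone. In the whole ependymal-like class 17 of 18 Hedgehog members were lower (median -0.53, percentile 0.13), among them Csnk1a1 at -0.54, Ift88, a ciliary transport gene, at -0.67 (-0.85 to -0.49) and Ptch1 at -0.54 (-0.82 to -0.25). Summed in cluster 3 alone Hedgehog genes were at -0.35 (-0.46 to -0.25) and Wnt signalling at -0.45 (-0.55 to -0.34), so the lower value is not particular to Hedgehog genes. Oxidative phosphorylation was higher in the whole ependymal-like class (27 of 29, 1.01). In endothelial-like cells 17 of 18 interferon response genes were higher (1.03, percentile 100), with Bst2 at 242 against 45.1 CPM (2.42, 1.69 to 3.27), Isg15 at 2.21 and H2-D1 at 1.06, and Tspo, a mitochondrial outer membrane protein, was 276 against 45.1 (2.61, 1.88 to 3.46). Cldn5, a tight junction protein, was at 1.53 (1.36 to 1.69), and Ankrd37, at 0 in wild type saline, was at least 4.30-fold higher.

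Microglia-like cells of mutant saline held more Tyrobp (1.87, 1.45 to 2.32) and Trem2 (1.52, 1.05 to 2.02), which form a receptor complex, and less Cx3cr1 (-0.55, -0.77 to -0.33). They also held more Ccl12 (3.26, 2.03 to 4.88) and Tspo (0 in wild type saline, at least 4.45-fold). Tyrobp, Trem2 and Cx3cr1 were chosen after their values were seen, so no state of these cells is read from them. Border macrophage-like cells held more Ccl2 (5.60, 3.11 to 10.91) and Ccl12 (3.83), and less Hist1h2ap (-2.49). Among the top genes of the other classes were Bst2 (3.37) and Txnl4a (4.34) in choroid plexus-like, and Cyba (3.38) in astrocyte-like cells. They were Ptgds (2.63) and Vkorc1 (3.25) in fibroblast-like, Ubb (2.15) and Tm2d2 (2.87) in oligodendrocyte-like, and Hist1h2ap (4.79) and Ubb (2.52) in precursor-like cells. Gkn3 (3.47) and Tmem258 (at least 5.30-fold) led in pericyte-like, Sln (at least 7.89-fold) and Slc24a5 (at least 6.99-fold) in lateral habenula neuron-like, Cox5a (at least 4.38-fold) and Fth1 (2.07) in cortical or hippocampal neuron-like, and Egr1 and Fosb in ependymal-like cells. The lowest genes of each were drawn from Sec61a1, Pde6a and Mc1r, apart from Hist1h2ap above.

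With nicotine in the libraries labelled wild type, medial habenula neuron-like cells showed higher ribosomal, oxidative phosphorylation and neurokinin transcripts, and lower potassium channel transcripts. The nicotine side holds 72 cells with 54376 UMIs, against 3206 cells, and the ratios compare 2 libraries, not conditions. Of the 72 cells 63 lie in cluster 0 and 9 in cluster 11. Their share of that library falls from 2.58% to 1.04% at resolution 2. The next list of cluster 0 is neuroblast, at a mean log2 fold of 1.02 against 1.55, so different cells may stand behind these ratios. All 29 oxidative phosphorylation genes were higher (median 1.99, percentile 100; Cox8a 1802 against 290.1 CPM), as were all 34 ribosomal protein genes (2.14, percentile 100; Rpl37 3678 against 487). Tac2 was 1195 against 256 CPM (2.22, 1.84 to 2.59) and Tac1, the substance P precursor, was at 2.20 (1.40 to 2.92). Gpr151 was at -0.54 (-2.43 to 0.83). Tac2 and Tac1 are markers behind the class name. Size factors from the 378 genes with at least 20 counts in both libraries shift every log2 ratio here by -1.35, and scaling without Gm42418 by -0.19. Relative to the first shift, only the ribosomal and oxidative phosphorylation lists and genes above 1.35 stay higher, and every other higher list below falls under 0. The 378 genes needed 20 counts in the shallow library, which favours genes high there. Among genes of this class with at least 50 summed counts and counts in both libraries, the median log2 ratio was 0.03.

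Nicotinic receptor genes were too thinly counted for a direction, at -0.34 summed (-0.99 to 0.23; 2 of 8 higher), with Chrna3 at 147 against 135 CPM (0.12, -1.10 to 1.11), Chrnb4 at -0.05 (-1.93 to 1.33) and Chrnb3 at -1.22 (-4.27 to 0.65). Hedgehog genes were at -0.43 summed (-0.79 to -0.10), with Hhip at -2.11 (-5.16 to -0.25; 2 counts). Scube1 was at -0.84 (-1.79 to -0.03), Csnk1a1 at -0.27, Ptch1 at -0.36 (-2.24 to 1.01) and Sufu at 2.19 (0.26 to 3.64), which was at -0.63 over every barcode. Potassium and pacemaker channels were at -0.71 (-0.97 to -0.46), with Kcna2 at -1.94 (-3.39 to -0.82) and Kcnma1 at -0.65 (-1.01 to -0.32). Glycolysis was higher in 13 of 16 (0.99, with Gapdh at 2.08), heat shock in 10 of 14 (0.58, or 0.72 with the gene at 0 at its bound; Hspa8 0.84) and neuropeptides and their receptors in 10 of 17 (0.40, or 0.59 with the bound), and these 3 lists fall under 0 with size factors. Immediate early genes had a median of -0.52 with 8 members at 0, 1.03 with these at their bound, and 0.38 summed (-0.01 to 0.75), so no direction is given. Fos alone was 239 against 51.8 CPM (2.21, 1.27 to 3.02). Myelin genes were at -0.82 (-1.04 to -0.61).

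The highest genes of this comparison include Stmn1, a microtubule regulator, at 1839 against 154 CPM (3.58, 3.25 to 3.89), Hmgb2 at 3.77 (2.67 to 4.74) and Ppp1r14b at 3.74 (2.91 to 4.49). Ubb was at 3.10, Fau at 3.01, Slc24a5 at 4.08 (3.06 to 5.00), Hist3h2ba at 3.99 (3.06 to 4.84) and Ndnf at 4.31 (3.45 to 5.10), which was at -0.29 over every barcode. The lowest were Sec61a1 (-5.27, -7.14 to -3.91), Pde6a (1 count, -4.74, -10.05 to -2.26) and Mc1r (0 counts, at least 3.19-fold lower). Next were Myo5a, a myosin motor (0 counts, at least 4.34-fold), Usp15 (0 counts, at least 2.72-fold), Rbms3 (1 count, -3.99, -9.29 to -1.50), Rian (-1.84, -2.60 to -1.18) and Msi2 (-1.80, -2.58 to -1.11). Ribosomal protein transcripts were 8.29% and Gm42418 0.667% of all UMIs in the library labelled wild type, nicotine.

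In the other classes of that comparison, ependymal-like cells held more immediate early gene transcript with nicotine (13 of 21 higher; 0.77 summed, 0.67 to 0.88), and 1.95 (1.79 to 2.12) in cluster 3 alone, which holds 185 of 555 such cells against 822 of 1105 in wild type saline, with Ier2 at 147 against 11.5 CPM (3.67, 2.96 to 4.47) and Egr1 at 2.08 (1.60 to 2.58), or 5.08 and 3.03 in cluster 3 alone. They held less of all 16 presynaptic genes (-2.11) and all 12 channel genes (-2.17), which neurons make (-1.16 and -1.41 summed in cluster 3 alone), and fewer Hedgehog transcripts (11 of 14 lower, -0.81, percentile 5.17), and Thrsp was at 4.22 (2.90 to 5.90). Size factors shift this class by 0.21 and leave these directions. Endothelial-like cells had higher interferon response genes (1.36, percentile 99.9; Ifitm3 2905 against 923 CPM), Cldn5 (2.11, 1.88 to 2.33), Tspo (4.23, 3.41 to 5.15) and Ccdc85b (3.32), which stay above 0 after a shift of -1.05. Astrocyte-like cells were led by Dct, a melanin enzyme (0 in wild type saline, at least 291-fold higher), and Fth1 (3.09), and oligodendrocyte-like cells by Ifi27l2a (5.93, 4.00 to 9.02) and Fth1 (2.98). Txnl4a (5.25) and Eif3k (2.83) led in choroid plexus-like, Cox5a (at least 20.7-fold) and Elob (4.68) in cortical or hippocampal neuron-like, Ptgds (3.95) and Rbp4 (3.89) in fibroblast-like, and C1qb (3.12) and Cst3 (2.88) in microglia-like cells. The oligodendrocyte-like and cortical or hippocampal neuron-like cells come mostly from different clusters in these libraries, as given above.

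Under nicotine, mutant and wild type could be compared in ependymal-like and choroid plexus-like cells only. Ependymal-like cells of the mutant nicotine library held fewer oxidative phosphorylation and immediate early transcripts, and more Hspa5, Pdia4 and Kcnj10, than those of the library labelled wild type, nicotine. The comparison has 74 cells with 20811 UMIs against 555 cells with 888738. It has no replicate check, and 73 of the 74 mutant cells lie in cluster 3 while 370 of the others lie in cluster 8. Summed oxidative phosphorylation was at -0.98 (-1.17 to -0.78; 26 of 29 lower; Cox8a 817 against 1958 CPM, Cox6c -0.99) and immediate early genes at -1.07 (-1.88 to -0.36; 16 counts; 11 of 12 lower), or -2.11 in cluster 3 alone. Jun was at -2.44 (1 count, -7.75 to 0.06), Fos at -0.86 (-3.15 to 0.70; -2.02 in cluster 3) and Jund at -0.11. The unfolded protein response was at 0.50 (0.21 to 0.77; 7 of 12 higher), with Hspa5, the chaperone of the endoplasmic reticulum, at 1729.9 against 1057 CPM (0.71, 0.19 to 1.19) and Pdia4, a disulfide isomerase, at 1.92 (1.22 to 2.55), but Hsp90b1 at -1.04 (-2.11 to -0.16). Size factors shift every ratio of this class by -0.26, which leaves the directions of these summed lists.

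Hedgehog transcripts summed to 0.75 (0.17 to 1.27; 5 of 8 higher) in the same comparison, with Csnk1a1 at 1.01 (-0.02 to 1.87), Spop at 1.61 (0.26 to 2.71), Gsk3b at 1.21 (-0.27 to 2.37) and Hhip at 0 in mutant nicotine and 3 counts in the other library. Astrocyte transport genes were at 0.82 (0.48 to 1.14; 0.23 in cluster 3 alone), with Kcnj10, a potassium channel, at 865 against 239.7 CPM (1.85, 1.07 to 2.55; 2.72 in cluster 3). Heat shock was at 0.33 (0.19 to 0.47; Hsp90aa1 0.41; 0.98, 0.82 to 1.14 in cluster 3 alone) and ribosomal proteins at -0.58 (28 of 34 lower, although Rps29 was at 0.60). Lower too were microglial activation at -0.67 (-0.99 to -0.36; Apoe -0.64; -1.12 in cluster 3), reactive astrocyte genes at -1.12 (-2.12 to -0.27; Vim -0.81) and myelin at -0.98 (-2.04 to -0.09; -2.76, -3.77 to -1.91 in cluster 3). Highest were Sec61a1 (3.68, 2.74 to 4.54; 2.78 in cluster 3), Trim37, a ubiquitin ligase, at 1682 against 278 CPM (2.60, 2.04 to 3.11), and Ahnak (2.32). They were followed by Snhg9 (2.08), Dnal1 (2.54), Lmo4 (2.00), Fnbp1 (2.70) and Dnah6 (1.78), a leading gene of cluster 3. Lowest were Fth1 at 2355 against 7603 CPM (-1.69, -2.13 to -1.29), Riiad1 (-2.68), a leading gene of cluster 8, Dad1 (2 counts, -3.30, -6.35 to -1.45), Pebp1 (3 counts, -2.91, -5.19 to -1.35), and 4 genes at 0 counts: Nme2 (at least 3.68-fold), Ptgds (3.37), Ndufb11 (2.88) and D8Ertd738e (2.86). In choroid plexus-like cells oxidative phosphorylation was at -0.86 and the unfolded protein response at 0.51 (0.29 to 0.72), Eif2s2 (2.61) and Nhsl2 (3.07) were highest, and Gng5 (1 count, -4.74, -10.04 to -2.26) and Elob (-3.44) lowest.

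With nicotine in the mutant libraries, ependymal-like cells held fewer immediate early, oxidative phosphorylation and mitochondrially encoded transcripts, with 74 cells against 1680. The 74 cells are those of the comparison under nicotine, so neither comparison is a check of the other. Immediate early genes were at -1.44 summed (-2.22 to -0.76; 17 counts; 22 of 24 lower, 17 of them at 0), with Fos at -1.79 (3 counts, -4.07 to -0.24; -1.15 in cluster 3) and Jun at -2.88 (1 count, -8.18 to -0.40). Oxidative phosphorylation was at -0.60 (-0.80 to -0.40; 24 of 29 lower; Cox8a -0.70) and mitochondrially encoded genes at -0.62 (mt-Atp6 -1.62; -1.05 in cluster 3 alone). The unfolded protein response was at 0.43 (0.15 to 0.69), with Hspa5 at 1729.9 against 939 CPM (0.88, 0.37 to 1.35) and Pdia4 at 1.11 (0.44 to 1.71), and heat shock at 0.43 (0.29 to 0.57; 0.89 in cluster 3). Size factors shift this class by -0.35, which leaves both lists above 0 by less than 0.1 log2 units. Hedgehog genes, at 0.39 (-0.17 to 0.90; Csnk1a1 0.80, -0.20 to 1.64), have no direction beyond counting error, and myelin genes were at -2.03 (-3.04 to -1.19; -3.18 in cluster 3).

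Among the highest single genes were Trim37 at 1682 against 225 CPM (2.90, 2.37 to 3.38), Sec61a1 (3.06, 2.21 to 3.80; 2.46 in cluster 3), Ccdc171 (3.72), Kcnc4 (3.61), Tmem248 (3.16), Xpnpep3 (3.13) and Ppp2r3c (3.39), most with under 10 counts in mutant nicotine. The lowest were Gng5 at 625 against 1877 CPM (-1.59, -2.50 to -0.81), Riiad1 (-2.38, -4.01 to -1.16), and, with 3 counts each, Pebp1 (-2.39, -4.67 to -0.84), Ndufa4 (-2.34, -4.62 to -0.79) and Cd9 (-2.33, -4.61 to -0.79). Also among the lowest were Ptgds, Ndufc2 and Ndufb3, at 0 counts and at least 3.24-fold, 2.45-fold and 2.17-fold lower. Choroid plexus-like cells were alike in the unfolded protein response (0.55, 0.33 to 0.75), heat shock (0.48), oxidative phosphorylation (-0.55) and immediate early genes (-1.16, -2.11 to -0.35), with Sec61a1 (3.82) and Pi4k2a (3.36) highest and Gng5 (1 count, -4.38, -9.69 to -1.90) and Ubb (-2.67, -3.98 to -1.62) lowest. In both pairwise comparisons the mutant nicotine library is the one with more Sec61a1 in CPM. Gm42418 is 7.43% of all its UMIs, but in its ependymal-like cells it stood at 5526 CPM, between 3326 in the library labelled wild type, nicotine and 9635 in mutant saline.

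The nicotine ratio in mutant minus that in wild type was negative for immediate early genes and oxidative phosphorylation and positive for the unfolded protein response in ependymal-like cells. Immediate early genes were higher with nicotine in wild type (0.77) and lower in mutant (-1.44), a difference of -2.21 (-2.90 to -1.52), or -3.06 (-3.77 to -2.36) in cluster 3 alone. Oxidative phosphorylation differed by -1.88 (-2.08 to -1.69), the unfolded protein response by 0.80 (0.53 to 1.07), Hedgehog genes by 1.25 (0.73 to 1.76) and heat shock by 0.38 (0.24 to 0.51). The last is 1.29 (1.13 to 1.45) in cluster 3 alone and -0.11 over every barcode. The Hedgehog value is not particular to that list in the class. GABA receptors differed by 1.13 (0.04 to 2.23), Wnt signalling by 1.01 (0.42 to 1.59) and astrocyte transport by 0.99 (0.66 to 1.31), while glycolysis differed by -0.80. In cluster 3 alone these 4 lists gave -0.36, 0.64, 0.12 and -1.44, and Hedgehog genes 1.00 (0.43 to 1.57). Choroid plexus-like cells gave -1.50 (-1.61 to -1.38) for oxidative phosphorylation, 0.90 (0.69 to 1.12) for the unfolded protein response and -0.48 (-1.32 to 0.35) for immediate early genes. Size factors shift the ependymal-like differences by -0.18 and turn no sign named here. These are values from 4 single libraries, and the same difference is 7.95 for Sec61a1 and 3.00 for Gm42418 in ependymal-like cells.

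**Figure D4:**
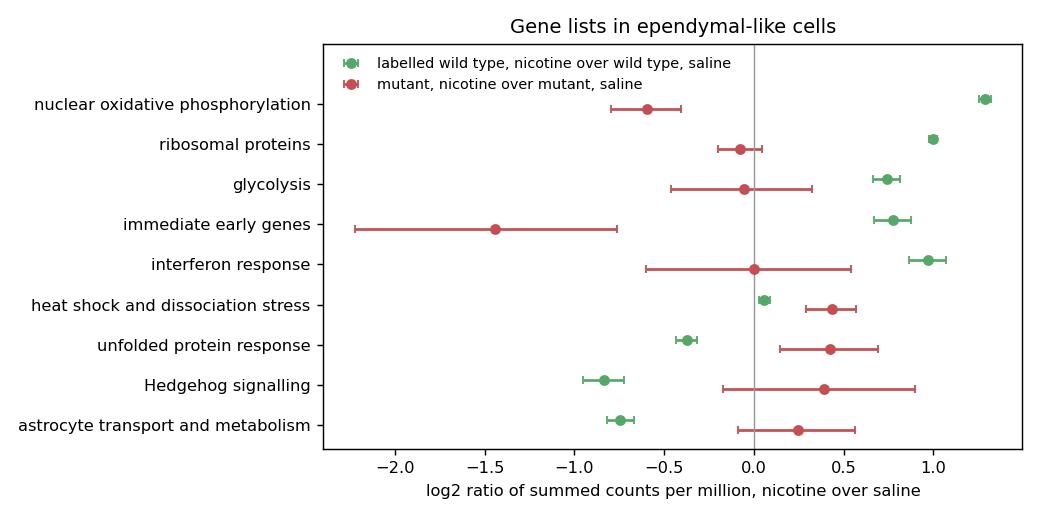
Log2 ratio of summed CPM, nicotine over saline (x axis), for 9 gene lists (y axis) in ependymal-like cells of the libraries labelled wild type and of the mutant libraries (colours), with 95% conditional binomial intervals that cover counting error only. Immediate early genes lie at 0.77 and -1.44 and oxidative phosphorylation at 1.29 and -0.60, signs that no scaling turns.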

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

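All tests in this part that weigh an explanation were chosen only after the result was seen. The differences in the next paragraph were not tested, since each group has 1 library, and stand out because the nicotine ratios of both genotypes have opposite signs in CPM.

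In ependymal-like cells the nicotine ratio in mutant minus that in wild type was -2.21 for immediate early genes, -1.88 for oxidative phosphorylation, 0.80 for the unfolded protein response, -1.20 for microglial activation (-0.31 in mutant, 0.88 in wild type) and -1.26 for reactive astrocyte genes (-0.91 and 0.34). In choroid plexus-like cells it was -1.50 for oxidative phosphorylation and 0.90 for the unfolded protein response, where the opposite signs (0.55 in mutant, -0.36 in wild type) do not hold with size factors, whose shifts of -0.24 and 0.48 put both ratios above 0. Apart from these, the barcodes of the mutant nicotine library that enter no comparison hold 14 Hhip counts, the only ones of that library. They stand out only as counts in barcodes that no comparison uses: over every barcode they make 23.5 CPM, below the upper bound of 56.0 for the 0 counts in the cells analysed.

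Sec61a1, Pde6a, Mc1r and Gm42418 are high in wild type saline and mutant nicotine and low in the other libraries over every barcode: Sec61a1 stands at 2735, 157, 67.9 and 5219.7 CPM over every barcode of wild type saline, mutant saline, the library labelled wild type, nicotine and mutant nicotine. In the cells analysed Sec61a1 was at 941 CPM in mutant nicotine and 2750 in wild type saline. There Gm42418 was at 6650 CPM in mutant nicotine, like the 6631 in the library labelled wild type, nicotine. With the labels as given, genotype alone or nicotine alone is argued against, since the log2 ratio of Sec61a1 in mutant over wild type is -4.12 under saline and 6.26 (6.07 to 6.46) under nicotine, and nicotine over saline is -5.33 in wild type and 5.06 in mutant. Whether free RNA of any source is behind these genes cannot be decided here. In wild type saline astrocyte-like cells held more Sec61a1 than medial habenula neuron-like cells (4476 against 2831 CPM, a log2 ratio of 0.66, 0.60 to 0.72). Free RNA adds counts per barcode, and the astrocyte-like cells are shallower (590965 UMIs in 864 cells against 3108872 in 3206), which raises their CPM. At these depths they also held no fewer Sec61a1 counts per cell. For Sec61a1 in wild type saline this argues against medial habenula neurons as the only source, but not against free RNA from other cells. A difference in library preparation or sequencing that acts on every cell remains open. The highest class ratio of Sec61a1 under saline, -3.66, lies below -2 as it would need to, but restates the pattern that prompted the check. In ependymal-like cells mutant nicotine over mutant saline was 3.06 (2.21 to 3.80) for Sec61a1 and -0.80 (-1.08 to -0.54) for Gm42418. Over the library labelled wild type, nicotine Gm42418 was at 0.73 (0.45 to 1.00). These ratios cannot decide it, since depth differs: 15 Sec61a1 counts in 74 cells with 20811 UMIs, against 451 in 1680 with 5226609. The filter also kept barcodes poor in Gm42418, at 6650 CPM against 82693 in the mutant nicotine barcodes left out. Genotype alone would give the same split if both nicotine libraries were exchanged, which is left open below, and an effect of genotype that depends on nicotine was not tested apart from the library.

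Hhip is lower in medial habenula neuron-like cells of mutant saline than of wild type saline. Less habenular RNA in these cells is argued against by the 8 nicotinic receptor subunit and assembly factor genes, which neither formed the clusters nor named them. Their median log2 ratio is 0.16, with none below -0.25 (0.19 and -0.09 in cluster 11). Scaling without Gm42418, which shifts every ratio of this class by -0.16, puts that median at -0.0048. A shift shared by genes of like count is argued against as well: Hhip lies at percentile 1.0 of the 500 genes nearest in count, whose median is -0.02. Free Hhip RNA that differs between the libraries stays open: less the level of astrocyte-like cells as a share of UMIs, the ratio in cluster 11 is -0.23 (-0.78 to 0.48) in place of -0.85, while with that level as counts per cell it is -0.75 (-1.12 to -0.38). In wild type saline Hhip was 22.5 CPM in ependymal-like, 23.9 in choroid plexus-like and 78.2 in endothelial-like cells, so the background is not a fixed share of UMIs. Free RNA adds counts per barcode, which makes counts per cell the nearer form, and in that form the ratio stays below 0. The astrocyte-like cells behind that level come from different clusters in these libraries, so free RNA as the whole cause is made less likely but not excluded. The genotype named by the labels was not tested apart from the library.

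Hhip in CPM is lowest in the library labelled wild type, nicotine, with an interval that overlaps that of mutant nicotine. An exchange of both nicotine libraries stays open, since together with a genotype difference it would give the split of Sec61a1 above. Hhip per summed habenular marker count in mutant nicotine over the other nicotine library was -0.42 (-1.43 to 0.52), from 14 and 34 counts. It has no sign beyond counting error. Single markers spread from -1.62 (Lrrc55, -2.63 to -0.68) to 1.11 (Tac2, 0.10 to 2.05), with 5 of 8 negative. Intervals per marker count carry the error of the Hhip counts but not of the marker counts (477 and 866 summed). They are therefore too narrow, and no sign is read from a single marker. Few habenular cells in that library could account for part of the low level, since per marker count the median log2 ratio to wild type saline is -0.78, but the markers spread from -2.69 (Gng8) to 0.03 (Lrrc55) with 7 of 8 negative, which keeps this open. Per 1000 summed marker counts Hhip was 78.6, 52.4, 39.3 and 29.4 in wild type saline, mutant saline, the library labelled wild type, nicotine and mutant nicotine. A single wrong label and an effect of nicotine on Hhip were not tested.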

How the results depend on the processing

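Scaling without Gm42418, removal of the highest-scoring doublets, cluster 11 only, cluster 3 only, list sums, Hhip less its astrocyte-like level and, for the comparison under saline, centring within each library were chosen after seeing the data; the others were fixed beforehand. No paired analysis was possible because each group has 1 library, so no group shares 2 or more replicate numbers with another. Over all alternatives, values of the comparisons' main results moved by less than their counting interval in 205 cases, moved further in 62 and turned sign in 7. For single gene ratios these were 858, 128 and 6 of 992, and for shares of the classes other than medial habenula neuron-like 267, 111 and 0 of 378. The cause was not tested for any value below unless a clause gives it.

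With at least 500 genes per cell, 44.7%, 78.3%, 57.9% and 0% of barcodes were analysed in wild type saline, mutant saline, the library labelled wild type, nicotine and mutant nicotine, so that mutant nicotine gives no other value. The medial habenula neuron-like share was 12.7%, 2.50% and 0.24% in the first 3, Hhip in wild type saline 88.6 CPM and the saline ratio of immediate early genes 0.11. With nicotine in wild type, Hhip turned from -2.11 to 0.15 and Pde6a from -4.74 to 0.29, on few cells. Shares with a UMI, taken over deeper cells by construction, were higher: Hhip in medial habenula neuron-like cells 29.3% (wild type saline) and 17.5% (mutant saline), Chrna3 there 26.9% and Ptch1 in astrocyte-like cells 34.4% (wild type saline). Thinned to 500 UMIs, by construction lower, they were 7.52%, 3.61%, 6.99% and 22.8%, and Hhip in astrocyte-like cells of mutant saline 0.86%.

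With at most 10% mitochondrial UMIs, 92.3%, 71.6% and 84.9% of barcodes were analysed in the first 3 libraries, the medial habenula neuron-like share was 10.5%, 3.41%, 0.41% and 0% in the 4, and immediate early genes under saline turned from 0.29 to -0.045. Removal of the highest-scoring doublets left 92.4%, 83.4% and 94.9% of barcodes and gave shares of 40.6% in wild type saline and 12.4% in mutant saline. The share was 34.8%, 8.12%, 1.04% and 3.45% at resolution 2, and 6.82%, 2.55%, 1.11% and 0% with centring within each library. Under 3 of these settings the class has lost most of cluster 0 (4259 cells), of which 1505 became unnamed and 2561 were left out with at least 500 genes, 2864 and 840 with at most 10% mitochondrial UMIs, and 3999 and 0 with centring, so that the shares and ratios under these settings rest chiefly on other cells of the class. Keeping doublets left all 31 main values it was run on within their interval, and resolution 0.5 all 4.

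Over every barcode, which mixes the cell classes by construction, the saline ratios were -1.92 for Hhip, 0.69 for immediate early genes and -0.32 for Hedgehog genes, and turned sign for nicotinic receptors (0.16 to -0.71), neuropeptides (0.28 to -0.72), Cd74 (-3.39 to 0.20), Chrna3 (0.45 to -1.22) and Chrna4 (0.42 to -0.80). With nicotine in wild type they were -1.69 for nicotinic receptors, -1.41 for neuropeptides and 0.44 for immediate early genes, and turned for Ndnf (4.31 to -0.29) and Sufu (2.19 to -0.63). The difference between genotypes for heat shock turned from 0.38 to -0.11.

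Size factors, which shift every ratio of a comparison alike, gave 126 CPM for Hhip in wild type saline. With nicotine in wild type they gave -1.84 for nicotinic receptors, -0.95 for neuropeptides and -1.87 for immediate early genes, and 0.20 for the heat shock difference. Without Gm42418 Hhip in wild type saline was 110.2 CPM, and the saline ratios were -0.0048 for nicotinic receptors (turned from 0.16), 0.11 for neuropeptides and 0.13 for immediate early genes. Without mitochondrial and haemoglobin genes Hhip in mutant saline was 28.1 CPM. With centring within each library the saline ratios were -0.77 for Hhip, 0.39 for neuropeptides and -0.15 for immediate early genes, which turned from 0.29, and in cluster 11 alone the last was 0.045. Less the level of astrocyte-like cells the saline ratio of Hhip was -0.37 with that level as a share of UMIs and -0.72 as counts per cell. With list members of at least 100 counts the Hedgehog median under nicotine was 1.11 in place of 0.31. In cluster 3 alone immediate early genes were -2.11 for genotype under nicotine and -3.06 for the difference between genotypes, and heat shock was 1.29 for the latter.

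Depth limits the mutant nicotine library most, with 65864 UMIs analysed in all. A gene at 0 in its ependymal-like cells can be at up to 177 CPM there, so that Hhip, at 3.38 CPM in those of the library labelled wild type, nicotine, was out of reach.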

Other observations

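Choroid plexus-like cells and an unnamed cluster carry differences outside the comparisons above. The unnamed cluster 16, led by Spp2, Sspo and Rbp4, made up 4.20% of wild type saline, 0.71% of mutant saline, 3.58% of the library labelled wild type, nicotine and 2.46% of mutant nicotine. Choroid plexus-like cells of mutant saline had potassium channel genes at a median log2 ratio of -1.23 and mitochondrially encoded genes at -0.74 against wild type saline. Haemoglobin transcripts, made by red blood cells, were 0.0389%, 0.504%, 1.35% and 0.0297% of all UMIs in wild type saline, mutant saline, the library labelled wild type, nicotine and mutant nicotine.

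Xist, which is made in female cells, and Ddx3y, from the Y chromosome, were both counted in each library: Xist 7529, 25699, 1532 and 132 times, and Ddx3y 166, 908, 27 and 50 times, in the same order. The labels give neither the sex nor the number of animals.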
